A study of Mus musculus with 8 samples.

How the data were processed

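RNA of soleus and flexor digitorum brevis muscle of CD-1 mice was measured on 8 spotted arrays of 9 by 16 spots, each comparing an RNA in Cy3 with another in Cy5. Per the labels, amplified RNA was made with an amino allyl message amplification kit and un-amplified RNA was copied from 10 micrograms of total RNA into amino allyl cDNA with an oligo(dT) primer. The labels name 4 dye-swap arrays and 4 loop arrays; they do not say how many animals gave the RNA. Each dye-swap pair exchanges the dyes of the same comparison, and in the loop every RNA meets 2 others.

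Per the file headers, the 8 channel files of the dye-swap arrays hold pixel intensity per spot from ImaGene 5.5, with background intensity beside it and not subtracted. These deposited files also give the area of the signal and the SD of the background as signal values, and a code for empty or poor spots. The deposited sheets of the loop arrays hold integral intensity per spot, which was taken as already background-subtracted, a background integral and a median pixel ratio of the channels. They also give the fraction of unsaturated pixels, as deposited, and a letter for usable spots. The software behind them is not given in the sources used here. The series table holds ratio values of Cy3 over Cy5 that the authors scaled by 1 factor per array, and per the labels it came from integral intensities by ImaGene and TIGR ExpressConverter. Matching these ratios to the spots placed all 132 probes on the grid, which gave 22 features of 6 spots and left 12 spots without a probe. Of the 20 named features, 19 had a mouse gene identifier; CAMTA1 did not. In 2 channel files, of 1 array, the image name in the header gave the other dye than the file name. The header was used. With it the authors' ratios of Cy3 over Cy5 matched that array in 97.6% of values, and with the dyes exchanged in at most 11.1%.

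All comparisons, tests, lists and the first set of alternatives were chosen before the data were examined. Dye-swap signals were corrected by the normexp method with an offset of 50, and loop integrals at or below 0 were set to the lowest positive value of their channel. Spots marked as empty or poor by the image software and spots without a probe were left out; saturated spots were kept, and between 0.862% and 4.46% of usable loop spots held saturated pixels. Log2 ratios of the 6 spots were averaged, and each array was centred on the median over features. The median over features of the SD between spots was between 0.0806 and 0.353 per array. Loess was an alternative only, since many of the features on this small array may differ.

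Fast and slow muscle were compared by limma 3.58.1 in R 4.3.3 on 3 replicate ratios per feature, namely the mean of each dye-swap pair and the dye-balanced loop estimate. All of these were present for 13 features, 2 of them for 8 and 1 for 1. Features with at least 2 ratios were tested against 0, two-sided, with moderated variances and Benjamini-Hochberg adjustment at 0.05. The amplified minus un-amplified difference and the comparisons within each kind of RNA rest on 2 such values each, one from the dye swap and one from the loop. Amplified and un-amplified RNA were compared on the 4 loop arrays with terms for muscle, amplification and dye. Agreement across features used Pearson's r and Spearman's rho with 100000 permutations, for which 1e-05 is the smallest p. The lists of slow and fast contractile genes were tested by fry where at least 3 members had every ratio, with camera (preset correlation 0.01, or estimated) as alternative. All 22 features are named, by a rule for arrays of 30 or fewer genes. The lists of glycolytic, muscle regulatory, housekeeping, connective tissue, endothelial and blood, nerve, fat and immune genes had 0 members on the array.

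The steps were tested on 50 simulated data sets of 22 features with 6 changed by 2 log2 units, at an SD between replicates of 0.3, 0.8 and 1.2. For fast against slow muscle, 100%, 88.7% and 42.7% of changed features were recovered, and 2%, 1.5% and 1.38% of unchanged ones were called. For amplified against un-amplified RNA, 98%, 45.7% and 20% were recovered, and 6.13%, 3.25% and 2.25% of unchanged ones were called. The simulated arrays had only usable spots, an even background on the dye-swap arrays and the same SD for all features. The data had unusable spots, uneven background and feature SDs from 0.10 (Myh7) to 2.55 (Myh4), so these rates may not hold for them. The simulations at an SD of 0.8 came closest to the pooled spread of the data. For fast against slow muscle, the pooled SD between replicate ratios was 0.825 in them and 0.790 in the data, and for amplified against un-amplified RNA the pooled SE was 0.501 and 0.517. Alternatives were loess (span 0.3), no centring, plain or no background subtraction, integral or median pixel signal, the median of the spots, mean intensities, keeping marked spots and leaving out features within 2 background SDs (dye swap) or below the 5th percentile of background integrals (loop). Further ones were all arrays in one fit, no moderation of variances, leaving out each array or replicate ratio, and the values of the series table, whose columns also carry the other pair labels. The fit of all arrays counted each array as independent, although the arrays of a dye-swap pair exchange the dyes of the same comparison. Its p-values and counts of calls may therefore overstate the evidence. The amplification labels of the table, its values with the labels of the files, and dyes by file name were added after the data were seen. The pixel mode ratios, spot areas and derived ratio sheets of the loop were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.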

Results

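The series compared RNA from a slow muscle, the soleus, with RNA from a fast muscle, the flexor digitorum brevis (FDB), of CD-1 mice aged 4 to 5 weeks. Each of the 8 arrays carried 20 named genes and 2 features without a gene name, with 6 spots per feature, and paired an RNA labelled with Cy3 with another labelled with Cy5. The RNA was either amplified before labelling or labelled without amplification as cDNA. In the dye-swap experiment, 2 arrays set fast against slow amplified RNA and 2 set fast against slow un-amplified RNA, with the dyes exchanged within each pair. In the loop experiment, 4 arrays joined slow amplified, slow un-amplified, fast amplified and fast un-amplified RNA in a ring.

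Of the 1056 gene spots on all arrays, 848 (80.3%) were usable in both channels. The first dye-swap pair, whose scanner files carry the amplified label, had the lower signal over background, with median spot signals between 1.75 and 4.64 times the background. In the second pair, whose files carry the un-amplified label, this ratio lay between 62.6 and 324. Phospholamban (Pln), a regulator of the calcium pump, had no usable ratio in either pair, and 7 further features had no ratio averaged over both dye orientations in the first pair. Of these, Myh4 and Myh6 had no usable ratio there, and the others had one on its second array only. The number of arrays limits the precision of every value given here.

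A doubt about the labels bears on each result that separates amplified from un-amplified RNA. The ratios in the series table of the amplified dye-swap samples matched the scanner files of the un-amplified samples, and the reverse, in 97.6% to 100% of values to within 0.0003 natural-log units. No other pairing of a table column with an array matched more than 11.1% of values. The labels of the scanner files were used, results with the labels of the table stand beside them, and the pairs are called the first and the second. The overall comparison of the muscles does not depend on this label. The p-values of the tests per feature measure the spread between these samples, which may be technical, since the labels do not say whether they came from separate animals. For fast against slow muscle, the replicate ratios came from amplified RNA, from un-amplified RNA and, in the loop, from both. Their spread, pooled over features, therefore also holds any effect of amplification on the ratio and any shrinkage of the first pair. A further exception is the test of amplified against un-amplified RNA within the loop. Its residual is the difference in amplification effect between the muscles, pooled over features, and not a spread between replicates. Those of correlations come from permutations across features.

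The main comparison asked which genes differed between fast and slow muscle. Parvalbumin (Pvalb), a calcium-binding protein of fast fibres, was 4.75-fold higher in fast muscle, with a mean log2 fast/slow ratio of 2.25 ± 1.33 (SD, n = 3 replicate ratios; adjusted p = 0.000223). Myh1, the myosin heavy chain of fast IIx fibres, was 3.29-fold higher (1.72 ± 0.91, n = 3, adjusted p = 0.00444). Myh7, the slow myosin heavy chain, was 8.07-fold lower in fast muscle, with a mean log2 ratio of -3.01 ± 0.10 (n = 2, adjusted p = 0.000112). Ldhb, the lactate dehydrogenase subunit typical of heart and slow muscle, was 3.90-fold lower (-1.96 ± 0.29, n = 2, adjusted p = 0.00667), and Tnnc1, the troponin C of slow and cardiac muscle, was 2.54-fold lower (-1.35 ± 0.39, n = 3, adjusted p = 0.0240). Each of these 5 genes kept its direction in every replicate ratio that could be formed. The means of Myh7 and Ldhb left out the first pair, where its second array alone gave -0.93 and -0.48. Their folds are therefore not directly comparable with those of Pvalb, Myh1 and Tnnc1.

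Of the 3 measured genes of the slow contractile list, Myh7 and Tnnc1 fell in fast muscle, and slow troponin I (Tnni1) had a mean log2 ratio of -0.71. The count was 2 of 3 both over all features and adjusted over the list alone. Of the 5 measured genes of the fast contractile list, 1 rose, Myh1, and 1 when adjusted over the list alone. The other fast genes had mean ratios above 0 without passing the test. These were the fast regulatory light chain Mylpf (0.47), troponin C (Tnnc2, 0.31), the IIb myosin heavy chain Myh4 (0.48) and troponin I (Tnni2, 0.12). The Myh4 mean joined a ratio of 2.28 in the second pair with -1.32 in the loop, and the Tnni2 mean joined 0.58 with -0.33. With all arrays in one fit both means turned negative, to -0.38 for Myh4 and -0.05 for Tnni2, and the Tnni2 mean was -0.01 under loess. The rotation test fry of limma gave an adjusted p of 0.0889 for the fast list, on its 3 members present in every ratio. It could not be run on the slow list, which had fewer than 3 such members. Leaving out the first pair gave the slow list, lower in fast muscle, an adjusted p of 0.00867 by fry, 0.0196 by camera at its preset correlation and 0.287 with an estimated correlation. Without that pair the adjusted p of the fast list by fry was 0.305.

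In the fast-type calcium-handling list, Pvalb was the measured gene and rose. For the slow-type list, Pln had 1 ratio, 0.06 in the loop, and no test. Calmodulin (Calm2, 0.81) and the calcineurin subunit Ppp3cb (-0.06), from the calcium-signalling list, did not pass the test over all features or adjusted over the list alone. Of the oxidative list, Ldhb fell and myoglobin (Mb, -0.60) did not pass, and 1 of 2 was called when adjusted over the list alone. Skeletal actin (Acta1), the measured member of the cytoskeletal list, had a mean log2 ratio of -1.02 ± 0.35 (n = 3, adjusted p = 0.112), and its ratios on the arrays of the second pair went opposite ways (-2.08 and 0.38); it passed over its list alone, where with 1 measured gene nothing was adjusted. The cardiac myosin heavy chain Myh6, from the smooth and cardiac muscle list, had a mean of -0.90 (n = 2, adjusted p = 0.343). The remaining features did not pass the test either. They were the muscle LIM protein gene Csrp3 (0.29), matrix Gla protein (Mgp, -0.03), the phosphatase subunit Ppp2ca (-0.05), the calmodulin-binding transcription activator CAMTA1 (-0.39) and the features of probes 19 to 24 (-0.19) and 97 to 102 (-0.04).

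**Figure D1:**
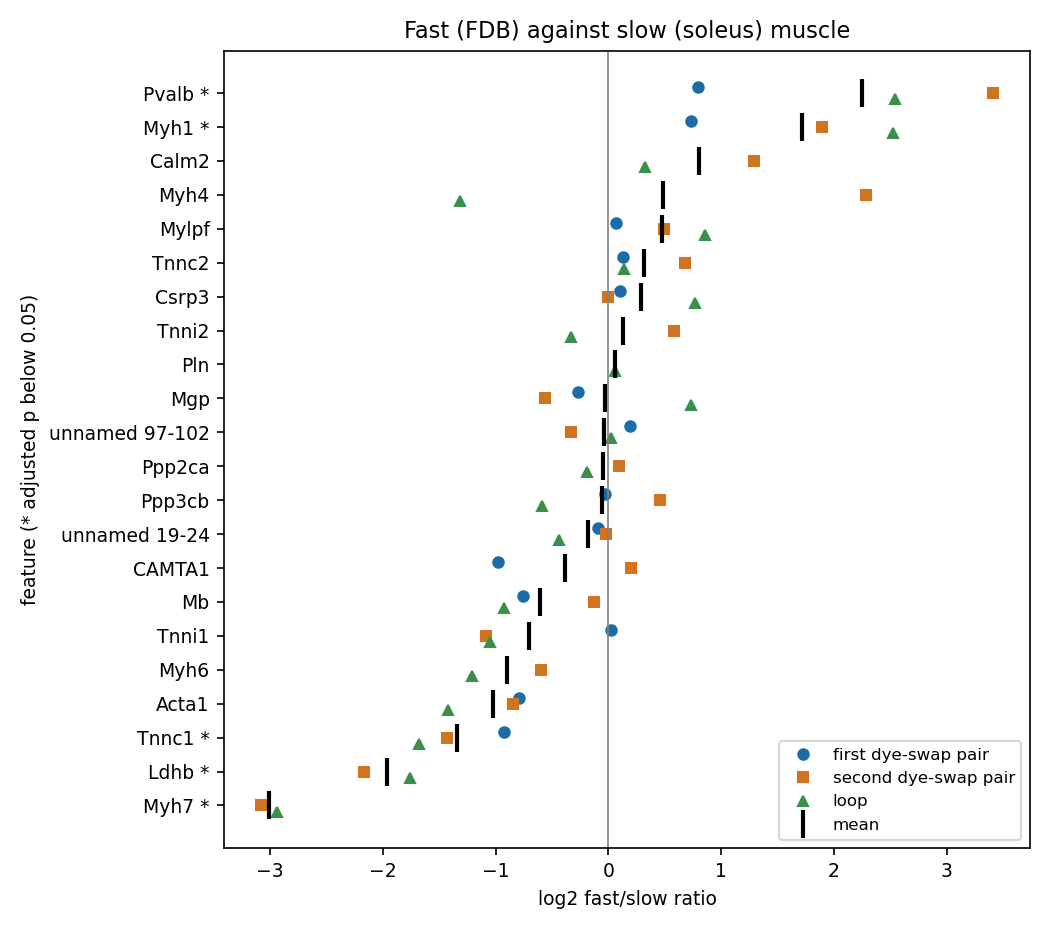
Log2 fast/slow ratio of each feature in the first dye-swap pair, the second dye-swap pair and the loop, with the mean of the available ratios as a black bar; asterisks mark adjusted p below 0.05. Pvalb and Myh1 lie to the right of 0 and Tnnc1, Ldhb and Myh7 to the left in every ratio shown.

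With limma, 5 of 21 tested features passed an adjusted p of 0.05, 2 higher and 3 lower in fast muscle, against 6 at an unadjusted p below 0.05. With no centring the median of all features moved by 0.19 and the same 5 features were called, as they were without the first pair. The mean of Pvalb was 2.97 without the first and 1.67 without the second pair, and with marked spots kept Myh7 had -1.79 and Ldhb -1.16. The calls rest on a variance pooled over all features, since a linear model with each feature's own variance called 0, with 3 at an unadjusted p below 0.05. Loess left Myh7 as the 1 call, leaving out the features near background kept Myh1 alone and added Acta1, leaving out the loop left Pvalb, and limma called none without the second pair or with the dyes of its second array taken from the file names (2 at an unadjusted p below 0.05 in each case). Under loess Pvalb had a mean of 1.89, Myh1 1.27, Ldhb -2.01 and Tnnc1 -1.08, and without the loop Myh1 had 1.31 and Tnnc1 -1.18. Myh7 and Ldhb had no test without the loop or without the second pair. With the features near background left out, 9 were tested, and Myh7, Pvalb, Ldhb and Tnnc1 were not among them. With all arrays in one fit 7 features passed, the same 5 with Acta1 (adjusted p = 0.0198) and Myh6 (adjusted p = 0.0363). That fit counted the arrays of a dye-swap pair as independent, so its p-values may be too small. With the dyes of the file names the means shrank to -1.60 for Myh7, 1.03 for Pvalb, -0.81 for Ldhb, 1.08 for Myh1 and -0.95 for Tnnc1. The authors' ratios of that array matched the dyes of the header and not those of the file names.

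The second comparison asked whether fast/slow ratios differed between amplified and un-amplified RNA. No feature passed limma's test with the labels of the scanner files. For Pvalb, the amplified minus un-amplified difference in log2 ratio was -2.62 in the dye swap and 2.44 in the loop. For Myh1 these differences were -1.17 and 1.42, and for Tnni1 they were 1.10 and -2.41. With the labels of the series table, Pvalb had a mean difference of 2.53 (SD 0.12, n = 2, adjusted p = 0.0174) and Myh1 one of 1.30 (SD 0.18, n = 2, adjusted p = 0.0492), both with larger ratios in amplified RNA. Tnnc1, Mb and the feature of probes 97 to 102 had the same adjusted p, 0.0525, with differences of -0.53, 0.58 and -0.53. The calls with the file labels numbered 0 of 13, with 0 at an unadjusted p below 0.05 and 0 by the linear model without pooling. With all arrays in one fit they numbered 0 of 21, where 1 had an unadjusted p below 0.05. That fit called Myh4 and Pvalb without the loop array that compared the kinds of RNA within slow muscle. It called the same genes without the loop array within fast muscle. With the labels of the table limma called 2 of 13, and 4 with all arrays in one fit (Myh7, Tnni1, Pvalb and Ldhb). With the ratios of the series table itself, which carry the same labels, it called 0 of 20, with 7 at an unadjusted p below 0.05 and a lowest adjusted p of 0.0625.

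The third comparison asked which features gave more signal from amplified than from un-amplified RNA, within the loop and relative to the median feature of each array. Fast troponin I (Tnni2) was 7.42-fold higher in amplified RNA (log2 2.89, SE 0.52, 4 arrays, adjusted p = 0.000156), Myh7 4.82-fold (2.27, adjusted p = 0.00178), Tnnc1 3.28-fold (1.71, adjusted p = 0.0115), Mb 2.79-fold and Acta1 2.71-fold (adjusted p = 0.0257 for both). Csrp3, a protein of the muscle Z-disc, was 7.71-fold lower (log2 -2.95, adjusted p = 0.000156) and Myh6 3.42-fold lower (-1.77, adjusted p = 0.0105). Of the unnamed features, that of probes 19 to 24 was 3.72-fold higher (adjusted p = 0.00749) and that of probes 97 to 102 was 2.76-fold lower (adjusted p = 0.0257). Each of these 9 had the same direction in slow and in fast muscle. Of the slow contractile list 2 of 3 rose (Myh7 and Tnnc1) and of the fast list 1 of 5 (Tnni2).

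**Figure D2:**
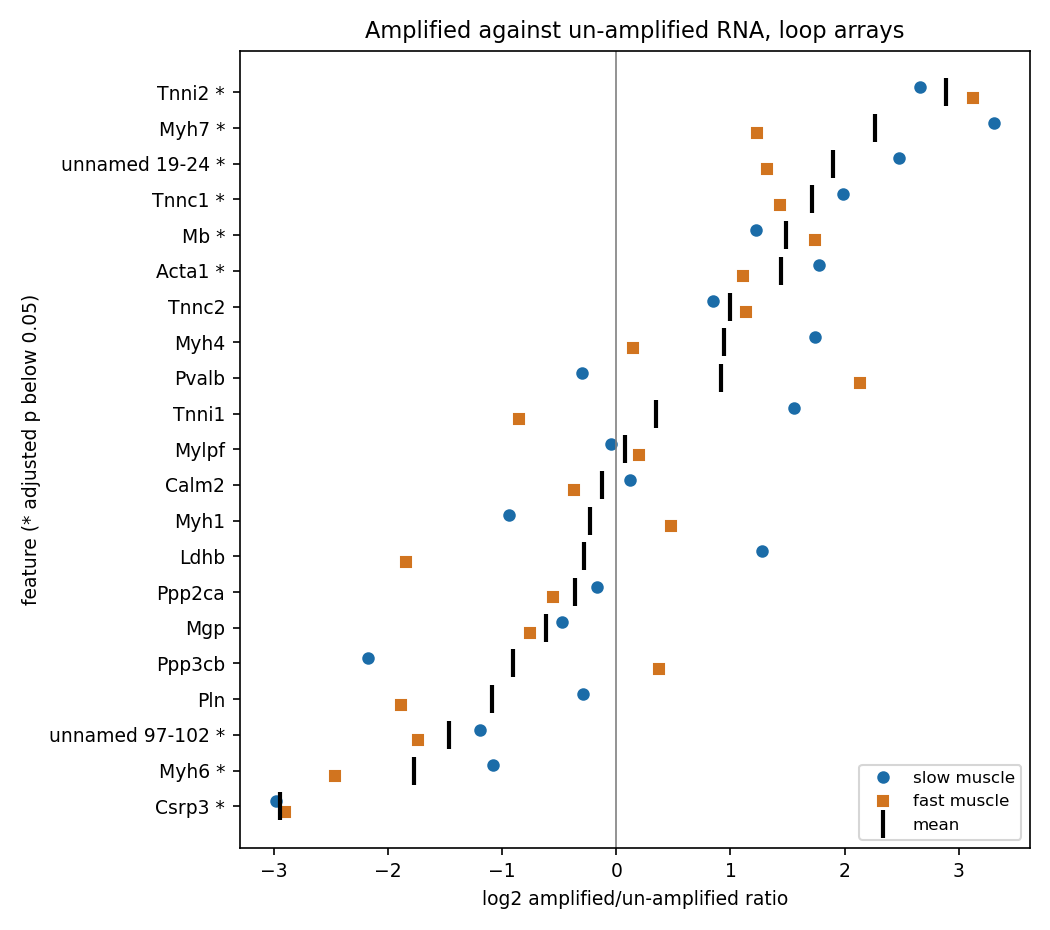
Log2 amplified/un-amplified ratio of each feature on the loop arrays, in slow muscle, in fast muscle and as their mean; asterisks mark adjusted p below 0.05. By the mean Csrp3 is lowest (-2.95) and Tnni2 highest (2.89), while in slow muscle Myh7 is highest (3.31); Ldhb and Ppp3cb lie on opposite sides of 0 in the muscles.

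With limma, 9 of 21 features passed, 6 higher and 3 lower, against 10 at an unadjusted p below 0.05. With all arrays in one fit 11 passed, the same 9 with Tnnc2 and CAMTA1. The variance was again pooled over features, and without pooling 0 were called, with 2 at an unadjusted p below 0.05. Loess left 0 calls by limma, with 6 at an unadjusted p below 0.05, and moved all 9 toward 0, Mb to 0.20, Acta1 to 0.27, Tnnc1 to 0.71 and Myh6 to -0.82. With no centring the median of all features moved by -0.63 and 4 calls were left (Tnni2, Csrp3, Myh6 and the feature of probes 97 to 102). Keeping the spots marked as unusable also left 4, of which 3 were among the 9.

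Fast and slow muscle were also compared within each kind of RNA. In amplified RNA, Pvalb had log2 fast/slow ratios of 0.79 in the first pair and 3.76 in the loop (mean 2.28, n = 2, adjusted p = 0.0865), and Myh1 had 0.73 and 3.24 (mean 1.98, adjusted p = 0.0962). Myh7 had a loop ratio of -3.98 and Ldhb one of -3.32; in the first pair they were measured on the second array only, at -0.93 and -0.48, and had no ratio averaged over both dye orientations. In un-amplified RNA, Myh1 (mean 1.85, n = 2), Myh7 (-2.49) and Tnnc1 (-1.42) had the lowest adjusted p, 0.126 for each, and Pvalb had a mean of 2.36 (adjusted p = 0.204). With the labels of the table, 4 of 20 features passed in amplified RNA, namely Pvalb (mean 3.58, n = 2, adjusted p = 0.000239), Myh1 (2.57, adjusted p = 0.00377), Myh7 (-3.53, adjusted p = 0.000239) and Ldhb (-2.74, adjusted p = 0.00266). In un-amplified RNA, Myh1 then had a mean of 1.27 and Tnnc1 one of -1.16 (adjusted p = 0.0598 for both).

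With the labels of the files, limma called 0 of 13 features in amplified RNA, with 2 at an unadjusted p below 0.05 and 0 by the linear model without pooling. In un-amplified RNA it called 0 of 20, with 3 at an unadjusted p below 0.05 and 0 without pooling; with the labels of the table it called 0 of 13, with 6. With all arrays in one fit and the file labels, Myh7 was called in amplified RNA, and Myh7, Myh1, Tnnc1 and Pvalb in un-amplified RNA. A call in one kind of RNA and not in the other shows no difference between them, which the second comparison tested.

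The last comparison asked how far fast/slow ratios from separate arrays went together across genes, which are not independent replicates. Over the 14 features measured in both dye-swap pairs, Pearson's r was 0.720 (permutation p = 0.00236, two-sided) and Spearman's rho 0.618 (permutation p = 0.0219), and 9 had the same sign. Pvalb had 0.79 in the first pair and 3.41 in the second, Myh1 0.73 and 1.90, and Tnnc1 -0.92 and -1.43. Without CAMTA1 and Tnnc1, the features farthest from the median of the first pair, r was 0.761. This kept Pvalb and Myh1, which had the highest ratios of the second pair among the 14. How far the r between the pairs rests on them was not computed. Over 13 features the mean of the pairs and the loop gave r = 0.893 (permutation p = 0.0001) and rho = 0.868 (permutation p = 0.00025), with 10 of the same sign, and r = 0.728 (permutation p = 0.0114) without Pvalb and Myh1. These were 2 of 4 such relations computed; the second pair against the loop gave r = 0.755 over 20 features and the first pair against the loop r = 0.861 over 13. Adjusted over the 4, the p of r was 0.00236 for the pairs and 0.000293 for the pairs against the loop, and that of rho was 0.0219 and 0.001. With integral signals, the r between the pairs was 0.533 (permutation p = 0.0564).

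**Figure D3:**
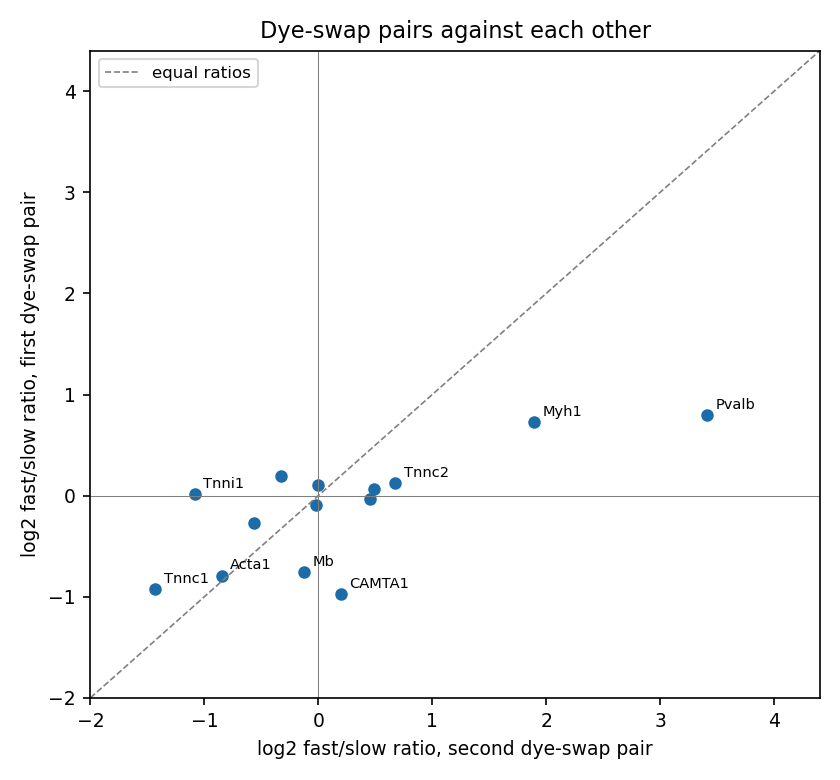
Log2 fast/slow ratio of each of the 14 features measured in both dye-swap pairs, first pair on the vertical and second pair on the horizontal axis; the dashed line marks equal ratios. Pvalb (0.79 against 3.41) and Myh1 (0.73 against 1.90) lie below the line.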

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

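All tests in this part were chosen after the results were seen, except the Myh4 test without background subtraction, which was written down before its result. The groups had at most 2 arrays, too few to test within a group for single arrays far from the others. In the fit of all arrays, 1 array left out at a time, calls were most without the loop array of slow amplified against slow un-amplified RNA. This held for fast against slow muscle and for amplification. Whether that array stood apart was not tested.

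The series table and the scanner files gave the dye-swap pairs opposite amplification labels. If the file labels were right and neither pair had shrunken ratios, amplified minus un-amplified differences should run alike in the dye swap and the loop. These are differences in fast/slow ratio, and across 13 features they ran opposite (Pearson's r = -0.822, permutation p = 0.00049), with Pvalb at -2.62 and 2.44. A candidate explanation is that the scanner files of the pairs were filed under each other's label. Features that were brighter in the first than in the second pair were those with less signal from amplified RNA in the loop (Spearman's rho = -0.825 over 18 features, permutation p = 5e-05). The labels of the table would fit both values. Ratios of the first pair pulled toward 0 by high background could also give opposite differences, whatever the labels. In the loop the amplified ratios were the larger ones, with an SD across 21 features of 1.89, against 1.01 for un-amplified ones. The r of -0.822 does not separate these explanations. An error in the loop labels stays open too, and no biological explanation was tested.

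Fast/slow ratios were smaller in the first pair than in the second, with SDs across 14 features of 0.561 and 1.24. High background on the first pair may have pulled its ratios toward 0, and this stays open. Its 4 features with signals at least 5 times the background had a slope of 0.440 on the second pair (95% interval -0.85 to 1.73), too wide to exclude equal ratios. Smaller ratios from un-amplified RNA are a second candidate, if the first pair was un-amplified as the table says. In the loop the SD across 21 features of un-amplified ratios was 0.535 of that of amplified ones.

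Myh4, the myosin heavy chain of fast IIb fibres, was higher in fast muscle in the second dye-swap pair and lower in the loop, a difference of 3.60 log2 units that was not tested. With the listed background added back, the loop ratio was -1.02, so subtraction in the un-amplified channels could not account for it. In the amplified channels of the arrays behind this ratio the median listed background was 0. The test therefore could not show an effect of subtraction there, which stays open. A few stray spots could not account for the difference, since the median of the spots gave -1.36. Hybridisation of other myosin transcripts to the Myh4 spots was not tested, and no biological explanation was tested.

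Fast troponin I (Tnni2) also lay above 0 in the second pair (0.58) and below 0 in the loop (-0.33), a difference of 0.91 log2 units that was not tested; its ratio of 0.19 on an array of the first pair rests on 1 usable spot. With the pairs as the table labels them, the feature of probes 97 to 102 was above 0 in every un-amplified and below 0 in every amplified ratio, with a mean difference of -0.53 (limma adjusted p = 0.0525).

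Among the 12 spots without a probe in the table, 2 lay above background in both channels of all dye-swap arrays. In the loop the mean signal of one from un-amplified RNA was 76.1 times that from amplified RNA, and its background-subtracted signal was 49.8 times as high in the first pair as in the second. For the other these ratios were 119 and 56.2, but 1 of its 4 amplified loop channels was listed at 0, and without that channel the ratio was 89.1. Median signals of gene spots were 3319 to 5219 in the first pair and 2821 to 7910 in the second. Both spots thus go with the labels of the table, and ratios pulled toward 0 would not account for brighter spots. What these spots measure is not given and no test was run, so the labels stay open.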

How the results depend on the processing

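The pair labels of the series table, its values with the labels of the files, and the dyes by file name were chosen after the data were seen. In fast against slow muscle, Pvalb, Myh1, Myh7, Tnnc1 and Ldhb kept their direction under every alternative that tested them, and passed in 20 of 24, 20 of 25, 20 of 22, 19 of 24 and 18 of 22. Their adjusted p reached 0.486, 0.486, 0.486, 0.475 and 0.546. The 9 features of amplified against un-amplified RNA also kept theirs in the 11 of 22 that changed their log2 values, though loess brought Mb from 1.48 to 0.20; the other settings could not change them. For fast against slow muscle the count fell from 5 to 1 under loess, 2 with dim features left out, 0 without moderation and 0 with dyes by file name, and was 7 with all arrays in one fit. Dropping dim features left 9 to test, without Myh7, Pvalb, Ldhb or Tnnc1; elsewhere the cause was not tested. For amplified against un-amplified RNA it fell from 9 to 0 under loess, 4 with no centring, 4 with marked spots kept and 0 without moderation, and was 11 with all arrays in one fit. For the amplified minus un-amplified difference it rose from 0 to 2 with the labels of the table, and to 4 with all arrays in one fit as well. In these settings Pvalb turned from -0.09 to 2.53 and 2.56. In amplified RNA the count rose from 0 to 1 with all arrays in one fit, 5 with the table values and labels, 4 with the labels of the table and 7 with those labels and all arrays in one fit. In un-amplified RNA it rose from 0 to 1 under loess, 3 with no centring, 2 without background subtraction, 2 with integral signals, 3 with median pixel signals, 3 with the median of the spots, 4 with all arrays in one fit and 8 with the table values and labels, where Myh4 turned from 0.88 to -0.997. With the table values and the labels of the files, limma called 2 in un-amplified RNA, where Myh4 had 1.05, and 0 in amplified RNA (7 at an unadjusted p below 0.05). The r between the pairs weakened from 0.720 to 0.533 with integral signals, 0.671 with dim features left out and 0.285 with dyes by file name, and stayed past the threshold at 0.666 under loess and 0.567 with the table values. The calls in the slow and fast contractile lists fell from 3 to 1 under loess and 1 with dim features left out. Leaving out 1 array or replicate ratio gave 0 to 8 calls for fast against slow muscle, 0 to 2 for the difference, 10 to 14 for amplification (11 without any 1 dye-swap array, which bears only on the variance there), 0 to 6 in amplified RNA, 0 to 9 in un-amplified RNA and 0 to 4 in the lists; single arrays were left out of the fit of all arrays, in which a lone array is assumed to vary like the others. Loess moved the median difference by 0.64 log2 units. Leaving out replicate ratios was not run where only 2 exist, and centring on housekeeping genes was not run, since the array has none. The filter on dim features removed no tested feature from the loop, so it says nothing there. Low signal over background limits the first pair, where 8 features had no ratio averaged over both dye orientations.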

Other observations

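The tests in this part were chosen after the results were seen.

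In the loop, slow and fast muscle shared much of the amplified/un-amplified pattern. Csrp3 had log2 ratios of -2.99 in slow and -2.91 in fast muscle, Tnni2 2.66 and 3.12, and Tnnc1 1.99 and 1.44. Across 21 features, the raw ratios of the arrays that compared the kinds of RNA within slow and within fast muscle gave Pearson's r = 0.573 (permutation p = 0.00727) and Spearman's rho = 0.577 (permutation p = 0.00748), with the same sign in 16. With the dye term in the model, as in the values given per feature, r was 0.607 (permutation p = 0.00351), with the same sign in 14. The same dye estimate, taken from all loop arrays, enters both values of a feature. They are therefore not independent, and the permutations do not allow for that. A yield of amplification particular to each feature and shared by both muscles may account for the shared part of the pattern. Both arrays carried amplified RNA in Cy3, so a dye bias would add to the r of raw ratios. Between averages over both muscles in opposite dye orientations, r was 0.955 (permutation p = 1e-05, the smallest that permutations can give). Both averages compare the same RNAs, so this r bears on dye bias and noise and not on a pattern shared by the muscles. Other features went apart, with Ldhb at 1.28 in slow and -1.84 in fast muscle and Ppp3cb at -2.18 and 0.37. The second comparison had no test for Ldhb, which had no dye-swap difference with both dye orientations, and Ppp3cb did not pass it (limma adjusted p = 0.992). With all arrays in one fit, the difference of Ldhb passed with the labels of the table, while with the labels of the files limma called 0 of 21 (lowest adjusted p 0.304, 1 at an unadjusted p below 0.05).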
